A study of Homo sapiens with 6 samples.

How the data were processed

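Total RNA of 6 samples of sorted MDA-MB-231 cells was analysed, 3 CD104high and 3 CD104low, all with a non-targeting guide and 10 µM forskolin for 14 days. The MLL3-mutant cells named in the design text were not analysed here. Per the labels, RNA was extracted with a microprep kit after sorting. Per the submitters' processing notes, FastQC, STAR 2.4.0, featureCounts 1.5.0 and DESeq2 1.30.1 were used with GRCh38.p13 (hg38), without their roles. The strand setting of the counting and any filter are not given in the sources used here, so overlapping and antisense genes cannot be told apart in the values.

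The table holds 15024 genes, with versioned Ensembl identifiers and symbols. Its row numbers run to 19893, and 4869 of them are not used here. No value is 0 and the lowest recovered count is 1 read, so genes with 0 reads in any library were not analysed here, which leaves out genes that are present in one group only. The per-library values have the unit signal: the authors deposited gene read counts divided by one size factor per library. The deposited log2 fold change equals the log2 ratio of the group means to within 0.02. The authors also deposited a standard error on the log2 scale, a test statistic used as a score and p-values with adjusted p-values, of which 1193 adjusted values are empty. From the values, whole reads were recovered by the size of 1 read in each library, with at least 99.99% of values within 0.1 of a whole number. For CD104high replicate 2 the size of 1 read was 0.993, close to 1. Its 1464 values under 20 were all whole multiples of that size and none was a whole number, but since that column is less certain, tests on counts stand only as alternatives. Recovered reads ranged from 52088604 to 56958065 per library.

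A count test had been planned for a table of counts. The deposited values are normalised, so limma 3.58.1 (R 4.3.3) with a mean-variance trend was applied to log2(value + 1), as planned for that case, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Genes entered with a value of at least 10 in at least 3 of the 6 libraries, regardless of group, which left 14343 genes and removed 681. Adjusted p-values are from limma unless another tool is named. Means and SDs are over the deposited values of 3 libraries. The labels call the replicates biological, without saying whether they came from separate cultures or sorts, and p-values measure the spread between these samples.

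Before the data were examined, 35 gene lists were fixed. Lists with at least 5 tested members, 33 in all, were tested with camera with a preset correlation of 0.01 and adjusted over the lists. Of these, 15 were called, 10 higher and 5 lower, and 0 held with an estimated correlation (lowest adjusted p = 0.0765). The estimated form refers its statistic to the 4 residual degrees of freedom of the fit, which the preset form does not, and so has little power here. With fry, which asks whether the members of a list move one way on balance, 21 lists were called. It sets the members against no change, and camera sets them against the other genes. A call by fry alone therefore does not show that a list moved more than other genes. The genes named were chosen by a rule fixed in advance. It took ITGB4, ITGA6, CD44, KMT2C, CDH1, EPCAM, VIM, ZEB1, SNAI1, SNAI2 and FN1, and the 10 higher and 10 lower genes with the largest fold change among called genes without group overlap and with a mean over the median of all tested genes (1323). It also took up to 4 members with the smallest p of each list, and 2 members with the highest mean of each list of other cell types. Some genes that the rule takes are not reported here. Gene spans are from GENCODE release 29 on GRCh38, matched without the version of the identifier for 14994 genes, of which 4244 had the same version, so a span may differ from the one the authors counted on.

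Same-numbered samples deviated together. The correlations across genes of their deviations from the group means were 0.17, 0.32 and 0.48 for numbers 1 to 3, each library correlated best with its own number, and the second principal component (26.0% of the variance, after 44.2% for the first, which parted the groups) set both libraries numbered 3 apart. The numbers therefore appear to pair the samples, from the data and not from a statement in the labels. The main test stayed unpaired, as planned, and a fit with the replicate number as a block was made as an alternative.

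Alternatives fixed in advance were size factors of DESeq2 in edgeR 4.0.16, no filter, each library left out in turn, the replicate block, DESeq2 1.42.0 and limma-voom on the recovered reads, pseudocounts of 0.1 and 5, a threshold of 0.01, a fold change of at least 1 on the log2 scale, and camera with an estimated correlation and fry. Alternatives chosen after seeing the data were edgeR with TMM, TMM and total-read scaling, limma without the trend, both libraries numbered 3 left out, camera with an estimated correlation in the fit with the block, and removal by loess (span 0.5) of the trend with the length and GC content of the longest transcript in each library. The loess removal was first run in a form that also subtracts the mean of each library. A second form that keeps the mean was added after the first was seen to shift the median of all genes, and both are reported. Length and GC content were known for 99.8% of genes.

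The scripts were tested on simulated data, with 200 changed genes among 14343. Of genes changed 1.5-fold, 65% were recovered, and of genes changed 2-fold, 75%, while 6.33% of calls were false. Of 20 unchanged lists, 0 were called by camera, and 1 shifted list was called. The simulated genes were drawn independently and without pairing of samples. The estimated correlation of the real lists reached 0.75, so the simulation does not measure false calls of lists with correlated members. The tools were Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.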

Results

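RNA was sequenced from MDA-MB-231 cells, an established line of triple-negative breast cancer that is largely mesenchymal in culture. The cells carried a non-targeting guide (sgNT) and had been grown for 14 days with 10 µM forskolin, which activates adenylyl cyclase and through it protein kinase A. They were then sorted on CD44 and on CD104, the integrin beta 4 subunit encoded by ITGB4. One group held CD44-positive cells high in CD104 (CD104high), which the design text describes as a hybrid epithelial-mesenchymal state, and the other CD44-positive cells low in CD104 (CD104low), described as mesenchymal. Each group had 3 libraries, named biological replicates 1 to 3. The deposited values held between 52088604 and 56958065 gene reads per library, and size factors lay between 0.971 and 1.03. EEF1A1 took between 1.03% and 1.16% of the reads as the gene with most reads. No 2 libraries were identical, and replicates of a group differed by more than the counting noise, with chi-square values per gene of 18.8 to 46.7.

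The comparison asked how the transcriptomes of the CD104high and CD104low cells differed after the same treatment. ITGB4 was 5.83-fold higher in the CD104high cells, and 28 of 38 tested genes of the type I interferon response (adjusted p = 0.0765 with an estimated correlation), HLA-B, HLA-C and the laminin gene LAMA5 rose with it. MYC, ODC1 and IL11 fell, as did 20 of 48 tested genes of G2 and mitosis, 14 of 43 S phase genes and 25 of 76 cytosolic ribosomal protein genes (adjusted p = 0.177, 0.367 and 0.43 with an estimated correlation). No list fixed in advance kept its call with an estimated correlation, a form of the test with little power here. Markers of the epithelial and mesenchymal states did not part cleanly between the groups, since JUP and PPL rose together with FN1, COL5A1 and S100A4, while VIM, ZEB1 and EPCAM did not pass the test. Of 14343 genes tested with limma, 1730 were higher (12.1%) and 1625 lower (11.3%) in CD104high at an adjusted p under 0.05. Of these, 333 rose and 35 fell by at least 1 on the log2 scale. The groups did not overlap for 5903 genes (41.2%), against 10% by chance.

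**Figure D1:**
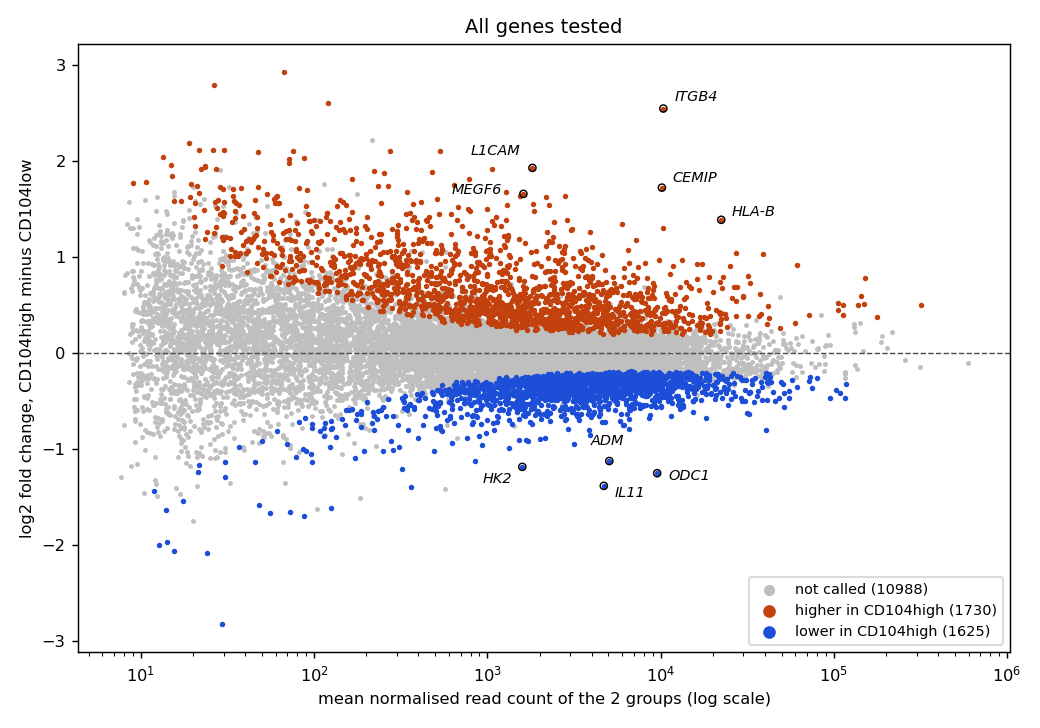
Each point is 1 of the 14343 genes tested, with the mean normalised read count of the 2 groups on a log axis and the log2 fold change of CD104high minus CD104low, on the value + 1 scale. The 1730 genes higher in CD104high are orange, the 1625 lower genes blue and the 10988 others grey, and ITGB4 stands at 2.54.

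ITGB4 (ENSG00000132470.14), the gene of the sort marker, had a normalised read count of 17659 ± 1766 (SD, n = 3) in CD104high and 3079 ± 743 in CD104low libraries. Its log2 fold change was 2.54 (SE 0.15, limma adjusted p = 4.1e-05), with the same direction in 3 of 3 numbered pairs. Its annotated span is chromosome 17, 75721328 to 75757818, on the plus strand of GRCh38. ITGA6 (ENSG00000091409.15), the alpha subunit that pairs with integrin beta 4, lies on chromosome 2, 172427354 to 172506282. It was 1.87-fold higher, at 15457 ± 1210 against 8272 ± 860 (adjusted p = 0.000306). CD44, on which both groups were gated positive, had 23950 ± 412 in CD104high and 26785 ± 1560 in CD104low (log2 fold change −0.16, SE 0.07, adjusted p = 0.113), and passed as lower only where the length and GC trend was removed together with library means (adjusted p = 0.0228, and 0.00615 with the replicate block). KMT2C, which encodes the histone methyltransferase MLL3, had 3984 ± 357 and 3938 ± 563 (log2 fold change 0.02, SE 0.11, adjusted p = 0.902).

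Among markers of the epithelial-mesenchymal transition named in advance, FN1 (fibronectin) was 1.73-fold higher in CD104high, at 28743 ± 2691 against 16975 ± 4932 (adjusted p = 0.00781). In limma without the mean-variance trend its adjusted p was 0.055. The other markers did not pass the main test. The intermediate filament gene VIM had a log2 fold change of 0.07 (SE 0.07, adjusted p = 0.469), and the adhesion gene EPCAM 0.09 (SE 0.16, adjusted p = 0.731). The transcription factor genes ZEB1, SNAI1 and SNAI2 had −0.01 (SE 0.08), −0.34 (SE 0.37) and 0.15 (SE 0.10). With the replicate block, and the length and GC trend removed together with library means, SNAI1 passed as lower (−0.43, adjusted p = 0.0373), and SNAI2 as higher only with the block and library means kept (0.23, adjusted p = 0.0267). CDH1 was not analysed here. Of 12 tested genes of EMT transcription factors, 4 were higher and 2 lower, both over all genes and adjusted over the list alone. FOXQ1 was 3.04-fold, RUNX2 1.39-fold and SOX9 1.32-fold higher, and FOSL1, a subunit of AP-1, fell by 0.32 on the log2 scale. The list was not called by camera (adjusted p = 0.382) but was by fry (adjusted p = 0.0187, camera adjusted p = 0.505 with an estimated correlation), and its median log2 fold change of −0.00072 and mean of 0.23 differed in sign.

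**Figure D2:**
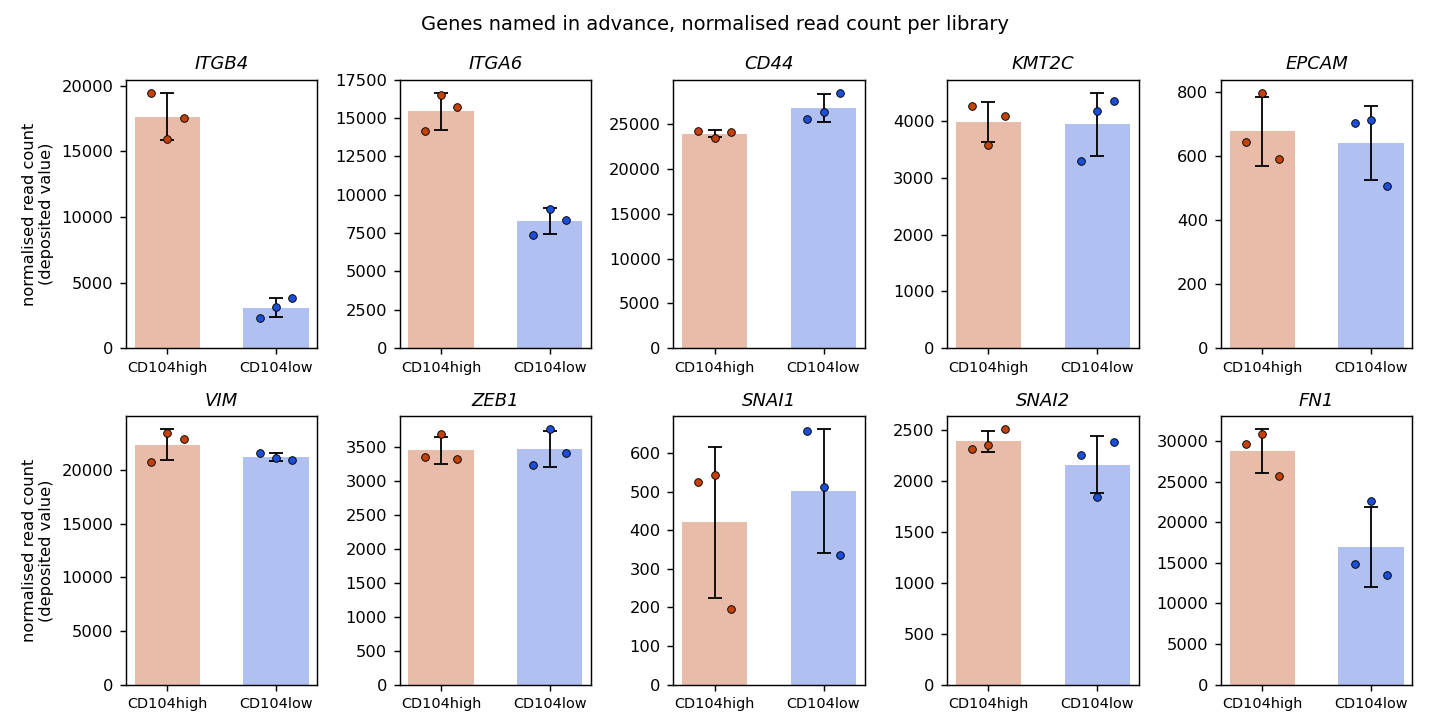
Normalised read count (deposited value) of 10 genes named in advance in each library, with bars for the group means, error bars for the SD (n = 3) and points for the libraries. The CD104high libraries lie above the CD104low libraries for ITGB4 and ITGA6 and also for FN1, and the groups lie close together for KMT2C, EPCAM, VIM and ZEB1.

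Among well-expressed genes called without group overlap, ITGB4 had the largest rise, followed by L1CAM, a neural cell adhesion molecule, which was 3.80-fold higher (2787 ± 997 against 852 ± 672, adjusted p = 0.0113). The call for L1CAM ended in limma without the mean-variance trend (adjusted p = 0.0684). CEMIP, which takes part in the breakdown of hyaluronan, was 3.30-fold higher (15573 ± 2217 against 4770 ± 1086, adjusted p = 0.000167). MEGF6, VSTM2L, GGT5, ANXA8, SLC37A2, SORBS2 and ALPP were between 2.79-fold and 3.15-fold higher. The call for ALPP also ended without the trend (adjusted p = 0.0557), and ANXA8 and ALPP have near-identical relatives whose reads may have been split between copies. In the other direction, IL11, a cytokine of the IL-6 family, was 2.61-fold lower (2599 ± 302 against 6800 ± 1009, adjusted p = 0.000148). ODC1, the rate-limiting enzyme of polyamine synthesis, was 2.38-fold lower (5634 ± 422 against 13469 ± 1777, adjusted p = 0.00013). HK2, a hexokinase, was 2.27-fold lower, and ADM, which encodes adrenomedullin, 2.18-fold lower. INSYN2B, CCDC86, SLC7A2, DUSP1, CHORDC1 and AEN were between 1.86-fold and 1.99-fold lower.

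Of 38 tested genes of the type I interferon response, 28 were higher, 0 lower and 10 did not pass over all genes, and 32 were higher and 1 lower adjusted over the list alone. The median log2 fold change was 0.87, and camera called the list (adjusted p = 2.03e-16), with adjusted p = 0.0765 with an estimated correlation. IFIT3 was 2.42-fold higher (4306 ± 263 against 1782 ± 166, adjusted p = 6.4e-05), IFIT2 2.61-fold, the helicase gene DDX60 2.52-fold and STAT2, a signal transducer of the type I interferon receptor, 1.99-fold. Of 36 genes of the interferon-gamma response and antigen presentation, 23 were higher and 0 lower over all genes, and 29 higher and 1 lower adjusted over the list alone. That list had a median of 0.73 (camera adjusted p = 2.34e-13, adjusted p = 0.132 with an estimated correlation), and 1 tested gene stood in both lists. HLA-B, a class I antigen-presenting molecule, was 2.61-fold higher (32363 ± 1641 against 12395 ± 915, adjusted p = 3.2e-05), HLA-C 2.24-fold and HLA-F 3.69-fold. CD74, the invariant chain of class II molecules, was 2.02-fold higher. HLA genes are paralogs, and the annotated spans of HLA-B and HLA-C overlap on chromosome 6, so the division of reads between them is uncertain.

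Of 15 genes of hemidesmosomes and laminin-332 adhesion, 8 were higher and 0 lower over all genes and adjusted over the list alone, with a median of 0.52 (camera adjusted p = 5.28e-05, adjusted p = 0.176 with an estimated correlation). This list holds ITGB4, the sort marker, and so is not independent of the sort. LAMA5, a laminin alpha chain, was 1.71-fold higher. Of 22 matrix proteases and inhibitors, 8 were higher and 2 lower, or 10 higher and 2 lower adjusted over the list alone (median 0.25, camera adjusted p = 0.00199, adjusted p = 0.176 with an estimated correlation). The members with the smallest p were 2 inhibitors, TIMP3 (2.23-fold higher) and TIMP2 (1.5-fold higher), and the proteases ADAM8 (1.95-fold) and ADAMTS12 (1.52-fold).

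Epithelial and mesenchymal lists both lay above 0. Of 37 genes of epithelial adhesion and junctions, 11 were higher, 2 lower and 24 did not pass, and 13 were higher and 2 lower adjusted over the list alone (median 0.24, camera adjusted p = 0.0179, adjusted p = 0.177 with an estimated correlation). PPL and JUP, which encode the desmosomal proteins periplakin and plakoglobin, were 2.86-fold and 2.32-fold higher, and the protease inhibitor genes SPINT1 and SPINT2 2.77-fold and 1.47-fold. Of 28 mesenchymal markers, 9 were higher and 3 lower, or 11 and 5 adjusted over the list alone (median 0.36, camera adjusted p = 0.0298, adjusted p = 0.177 with an estimated correlation). COL5A1 was 1.90-fold, S100A4 2.05-fold and FBN1 1.67-fold higher. Without CD104high replicate 1 the adjusted p of the mesenchymal list was 0.0615. Of 24 TGF-beta response genes, 12 were higher and 2 lower over all genes and adjusted over the list alone (median 0.28, camera adjusted p = 0.0164, adjusted p = 0.193 with an estimated correlation). PMEPA1, an inhibitor of the pathway, was 2.16-fold higher, LTBP2 1.88-fold and the receptor gene TGFBR2 1.49-fold, while CCN2 fell by 0.53. After removal of the trend with transcript length and GC content with library means kept, the medians of the epithelial, mesenchymal and TGF-beta lists were 0.18, 0.40 and 0.26, and their adjusted p 0.0758, 0.0836 and 0.0605. With the replicate block as well, the mesenchymal and TGF-beta lists were called and the epithelial list was not (adjusted p = 0.0568). In the form that also moves library means all 3 were called.

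Of 10 tested keratin genes, 4 were higher and 0 lower over all genes and adjusted over the list alone (median 0.24, camera adjusted p = 0.0192, adjusted p = 0.43 with an estimated correlation). KRT19 was 1.32-fold higher, at 26688 ± 292 against 20155 ± 669 (adjusted p = 0.00194). KRT7, KRT81 and KRT86 were 1.3-fold, 1.24-fold and 1.43-fold higher, but each of these 3 lost its call without CD104high replicate 1 (adjusted p = 0.11, 0.0831 and 0.0956) and without CD104low replicate 2 (0.0819, 0.0501 and 0.0743). KRT7 and KRT81 also lost it without CD104low replicate 3 (0.0671 and 0.0551), and KRT7 without CD104high replicate 2 (0.0639). Removal of the length and GC trend together with library means took KRT7 from 0.38 to 0.22 (adjusted p = 0.0647) and KRT81 from 0.31 to 0.15 (adjusted p = 0.0964) on the log2 scale, and both kept their call with library means kept. All 3 lost it in limma without the mean-variance trend (adjusted p = 0.0923, 0.0704 and 0.0598), and KRT7 and KRT81 without both libraries numbered 3 (0.05 and 0.0515). The annotated span of KRT86 holds KRT81 on the other strand and reaches into KRT7, so these 3 counts may share reads. The call of the keratin list ended without CD104low replicate 3 (adjusted p = 0.124) and without both libraries numbered 3 (adjusted p = 0.143). It also ended with the length and GC trend removed, at a median of 0.11 (adjusted p = 0.0538), or 0.19 with library means kept (adjusted p = 0.0513). Of 7 genes of basal and stratified epithelium, 1 was higher in both counts, adjusted over the list alone as well: S100A2, at 2.4-fold (adjusted p = 0.0013). That list was not called (median 0.59, camera adjusted p = 0.136), but was called with the replicate number as a block (adjusted p = 0.0416) and by fry (adjusted p = 0.0441). With an estimated correlation in the fit with the block, a form that called 0 lists, its adjusted p was 0.454. TRIM29, a member with a log2 fold change of 0.59 (SE 0.44, adjusted p = 0.36), also passed with the block (adjusted p = 0.00147) and without both libraries numbered 3 (adjusted p = 0.00985). TGM1, with 0.70 (SE 0.29, adjusted p = 0.103), passed with the block (adjusted p = 0.0343) and without CD104low replicate 1 (adjusted p = 0.0385).

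Of 48 genes of G2 and mitosis, 20 were lower and 0 higher over all genes, and 26 lower and 1 higher adjusted over the list alone (median −0.22, camera adjusted p = 1.83e-08, adjusted p = 0.177 with an estimated correlation). PLK1, a mitotic kinase, fell by 0.46 (SE 0.06, adjusted p = 0.00126), and CDC20, an activator of the anaphase-promoting complex, by 0.61 (SE 0.09, adjusted p = 0.00165). Of 43 S phase genes, 14 were lower and 0 higher in both counts, adjusted over the list alone as well, and 42 had a log2 fold change below 0 (median −0.21, camera adjusted p = 1.74e-07, adjusted p = 0.367 with an estimated correlation). CDCA7, a target of MYC, fell by 0.63 and TIPIN, a replication fork protein, by 0.54. Of 13 histone genes of the replication-dependent list, 3 were lower and 1 higher over all genes and adjusted over the list alone (median −0.38, camera adjusted p = 0.00847, adjusted p = 0.192 with an estimated correlation). H1-2 was 1.81-fold and H2BC12 1.65-fold lower. With the length and GC trend removed together with library means, the histone list had an adjusted p of 0.0854, and with library means kept it stayed called at a median of −0.36. The median of −0.38 in the first form is that of a member without a matched length, which was not corrected, and so does not measure the change. Histone genes are near-identical copies.

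Of 76 cytosolic ribosomal protein genes, 25 were lower and 0 higher over all genes, 38 were lower adjusted over the list alone, and 74 had a log2 fold change below 0. The median was −0.24 (camera adjusted p = 5.42e-12, adjusted p = 0.43 with an estimated correlation, fry adjusted p = 0.0774), and −0.14 without CD104low replicate 1, the library with the highest level of these genes. RPL6 fell by 0.42, RPS2 by 0.47 and RPSA by 0.47, and reads shared with processed pseudogenes make single values uncertain. Of 20 genes of the MLL3/MLL4 complex and COMPASS family list, 5 were lower and 0 higher in both counts, adjusted over the list alone as well (median −0.13, camera adjusted p = 0.021, adjusted p = 0.177 with an estimated correlation, and adjusted p = 0.0908 without both libraries numbered 3). Of these 5, EZH2, EED and SUZ12 belong to the opposing Polycomb complex PRC2 and not to COMPASS, so WDR5 and PAXIP1 were the 2 other members that passed. WDR5, a core subunit of COMPASS complexes, fell by 0.33 (SE 0.07, adjusted p = 0.00661). PAXIP1 fell by 0.28 (adjusted p = 0.0249), with adjusted p values of 0.0694 to 0.0907 where its call ended without 1 library. EZH2 fell by 0.32 (adjusted p = 0.0173). Its log2 fold change was −0.29 without CD104high replicate 1 (adjusted p = 0.0738) and −0.29 without CD104high replicate 2 (adjusted p = 0.0718), and its call also ended in limma without the trend (adjusted p = 0.0659). EED fell by 0.26 (adjusted p = 0.0414), but had −0.13 with the length and GC trend removed and library means kept (adjusted p = 0.201), and its call ended without any 1 of 4 libraries (adjusted p = 0.088 to 0.136). Of 25 cholesterol synthesis genes, 4 were higher and 0 lower in both counts, adjusted over the list alone as well (median 0.14, camera adjusted p = 0.0448, adjusted p = 0.673 with an estimated correlation). TM7SF2, a sterol reductase, was 1.88-fold higher (adjusted p = 0.000214). The call of this list ended without CD104high replicate 2 (0.0686) or 3 (0.244), and without CD104low replicate 1 (0.0592) or 3 (0.0785), values that are adjusted p. Its median was 0.086 and 0.040 without CD104high replicate 2 and 3. The call also ended with the length and GC trend removed together with library means (median 0.050, adjusted p = 0.081), without both libraries numbered 3 (median 0.041, adjusted p = 0.239) and with fry (adjusted p = 0.211).

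**Figure D3:**
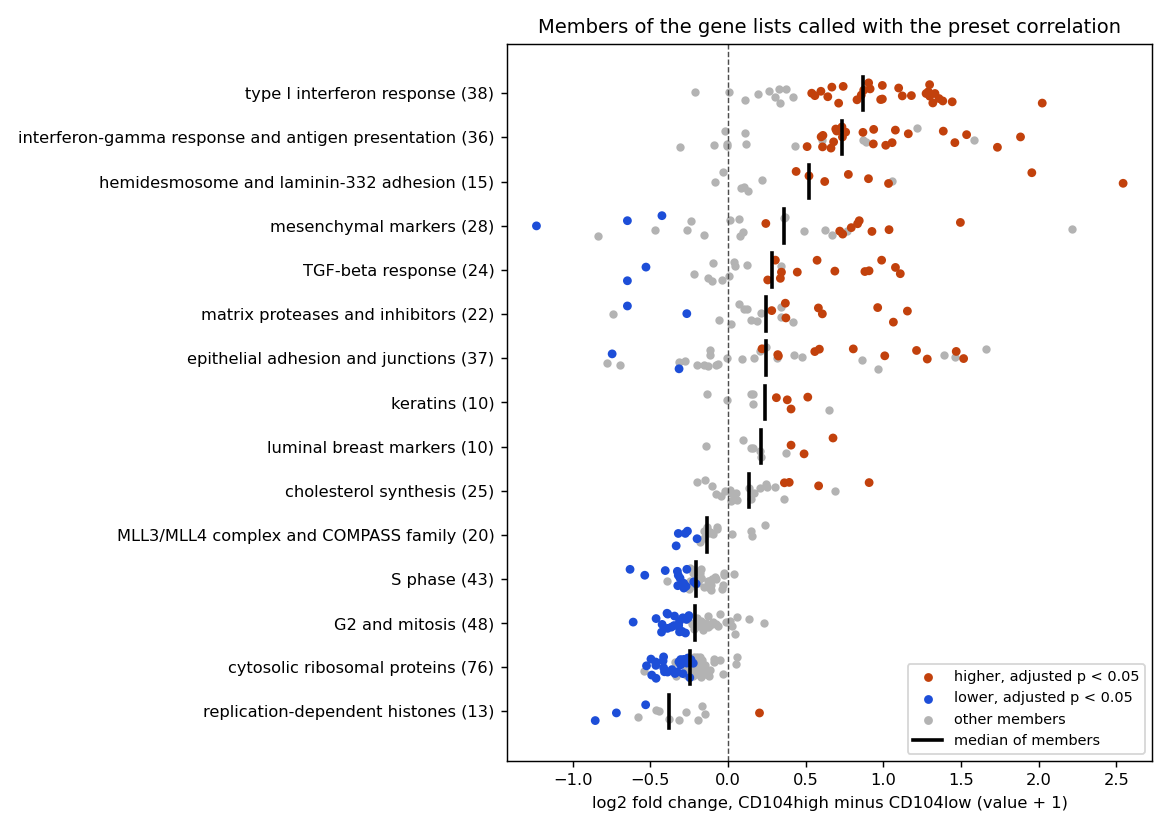
Log2 fold changes (CD104high minus CD104low, value + 1) of the tested members of the 15 gene lists called by camera with its preset correlation, with the number of members in brackets and a black line at each median. Members past an adjusted p of 0.05 are orange where higher and blue where lower, and the medians run from −0.38 for the histone genes to 0.87 for the type I interferon response.

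Lists of signalling pathways held genes that moved both ways. Of 15 Notch pathway genes, 4 were higher and 1 lower, or 5 and 1 adjusted over the list alone (median 0.28, camera adjusted p = 0.0592, fry adjusted p = 0.0187). The list was called without CD104high replicate 3 (adjusted p = 0.0406) and without CD104low replicate 2 (adjusted p = 0.0125), and with all libraries had adjusted p = 0.409 with an estimated correlation. The ligand gene JAG2 was 2.07-fold higher, at 2418 ± 117 against 1168 ± 37.0 (adjusted p = 0.000104). Of 18 Wnt pathway genes, 4 were higher and 2 lower over all genes and adjusted over the list alone (camera adjusted p = 0.305, fry adjusted p = 0.0116, camera adjusted p = 0.43 with an estimated correlation). The receptor gene FZD7 was 1.62-fold higher, and MYC, a transcription factor that drives growth, fell by 0.60 (5284 ± 74.3 against 8011 ± 491, adjusted p = 0.00046). Of 27 cAMP and CREB target genes, 4 were higher and 5 lower, or 6 and 5 adjusted over the list alone (camera adjusted p = 0.804). Its median was 0.08 and its mean −0.02. AREG, a ligand of the EGF receptor, was 2.08-fold higher and the phosphodiesterase gene PDE4B 1.62-fold, while CREB5 was 3.15-fold and CREM 1.58-fold lower. Of 15 genes of the MDA-MB-231 lung metastasis list, 4 were higher and 0 lower in both counts, adjusted over the list alone as well (median 0.39, camera adjusted p = 0.0513). PLAAT4 was 3.76-fold, EREG 1.89-fold and LY6E 1.63-fold higher. The tests took no account of whether a member is higher or lower in metastatic cells, so the rise gives no direction for metastasis. Of 19 axon guidance and neural genes, 6 were higher and 0 lower, adjusted over the list alone as well (median 0.22, camera adjusted p = 0.0513), among them NRP1 (1.66-fold) and SEMA3C (1.34-fold). With the replicate block the last 2 lists were called (adjusted p = 0.0246 and 0.0331). With an estimated correlation in that fit the adjusted p was 0.394 for both. That form called 0 lists, with 0.254 for the type I interferon response, so it cannot tell whether the calls of these 2 lists hold. Both were also called without CD104high replicate 3 (adjusted p = 0.00768 and 0.0182) and without CD104low replicate 1 (0.0228 and 0.0334), the metastasis list without CD104low replicate 2 (0.0288), and the axon guidance list without CD104high replicate 2 (0.0324). Both were called as well without both libraries numbered 3 (adjusted p = 0.0161 and 0.0144), with fry (0.0441 and 0.034), and with TMM scaling (0.0497 for both) or no filter (0.0469 for both). The metastasis list lay lower in both libraries numbered 3, by 0.65 in CD104high and by 0.64 in CD104low in mean log2 level, a shift within both groups.

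Of 24 NF-kB and inflammatory cytokine genes, 7 were higher and 2 lower over all genes and adjusted over the list alone (camera adjusted p = 0.161, and 0.0433 without CD104low replicate 1, and adjusted p = 0.673 with an estimated correlation and all libraries). ICAM1, an adhesion molecule bound by leukocyte integrins, was 1.91-fold higher and the growth factor gene CSF1 1.73-fold. Of 19 p53 target genes, 5 were higher and 1 lower in both counts, adjusted over the list alone as well (camera adjusted p = 0.17, fry adjusted p = 0.0286, camera adjusted p = 0.367 with an estimated correlation). CDKN1A, an inhibitor of cyclin-dependent kinases, was 1.90-fold higher and BBC3 1.77-fold, while AEN was 1.86-fold lower. Of 27 genes of the unfolded protein and integrated stress response, 5 were lower and 0 higher, adjusted over the list alone as well (camera adjusted p = 0.0854, 0.027 and 0.0291 without CD104low replicates 2 and 3, and adjusted p = 0.709 with an estimated correlation and all libraries). SLC7A11, the cystine transporter, was 1.69-fold lower and PSAT1, an enzyme of serine synthesis, 1.41-fold. Of 17 immediate early and handling stress genes, 6 were lower and 0 higher, adjusted over the list alone as well (camera adjusted p = 0.161, fry adjusted p = 0.034, camera adjusted p = 0.43 with an estimated correlation). The chaperone gene HSPH1 fell by 0.58 and JUN by 0.49.

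The remaining pathway lists had members on both sides and were not called. Of 26 hypoxia response genes, 4 were higher and 4 lower, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.253, 0.0386 without CD104high replicate 3, and adjusted p = 0.894 with an estimated correlation and all libraries), with ADM and HK2 lower and BNIP3L 1.34-fold higher. Of 20 glycolysis genes, 4 were higher and 3 lower, adjusted over the list alone as well (camera adjusted p = 0.804), with ALDOC 1.64-fold and PFKL 1.5-fold higher. Of 23 genes of MAPK pathway output, 5 were higher and 7 lower, or 7 and 7 adjusted over the list alone (camera adjusted p = 0.823), with the phosphatase gene DUSP5 1.66-fold lower. Of 23 YAP/TAZ target genes, 3 were higher and 2 lower, adjusted over the list alone as well (camera adjusted p = 0.892), with CCN2 and NT5E lower. Of 13 stem cell associated markers, 2 were higher and 2 lower, adjusted over the list alone as well (camera adjusted p = 0.961), with BMI1, a Polycomb gene, 1.37-fold lower. Of 19 NRF2 target genes, 2 were higher and 2 lower, adjusted over the list alone as well (camera adjusted p = 0.961), with AKR1C3 1.66-fold higher. The median of that list was −0.04 and its mean 0.09.

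Markers of other cell types were measured in the same libraries. Of 10 luminal breast markers, 3 were higher and 0 lower over all genes, and 4 higher adjusted over the list alone (median 0.21, camera adjusted p = 0.0188, adjusted p = 0.177 with an estimated correlation). KRT19 and MLPH (1.40-fold) were among them, and KRT8, the member with the highest level, had 63302 ± 763 in CD104high and 56946 ± 6703 in CD104low (log2 fold change 0.16, SE 0.09, adjusted p = 0.228). KRT8, ERBB2 and the endothelial gene EGFL7 passed as higher without CD104low replicate 1 (adjusted p = 0.0242, 0.0485 and 0.0188). ERBB2 had a log2 fold change of 0.20 (adjusted p = 0.0501, and 0.0264 with the replicate block). Of 3 tested leukocyte markers, too few for a list test, 1 was higher, adjusted over the list alone as well: CD14, at 548 ± 21.7 against 248 ± 13.2 (adjusted p = 0.000359). CSF1R had 89.1 ± 26.6 and 66.1 ± 7.59 (adjusted p = 0.297). Of 5 endothelial markers, 0 passed in limma in either count, adjusted over the list alone as well (camera adjusted p = 0.961). EGFL7 had 2358 ± 138 and 2031 ± 464, and ESAM 1384 ± 338 and 1853 ± 592, of which ESAM passed as lower with the replicate block (adjusted p = 0.00478) without CD104low replicate 3 (adjusted p = 0.0232) and without both libraries numbered 3 (adjusted p = 0.00897). Mitochondrially encoded mRNAs were not analysed here.

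The counts of higher and lower genes moved with single libraries. Without CD104high replicate 1, 1017 genes were higher and 799 lower, without CD104high replicate 2, 1120 and 901, and without CD104low replicate 2, 1278 and 1030. Removal of the trend with transcript length and GC content, which also shifted the median of all genes to −0.06, turned the split of 1730 higher and 1625 lower genes into 1395 and 3047, and with the mean of each library kept it was 1886 and 1968.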

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

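The counts of 1730 higher and 1625 lower genes kept within 1.5 times under edgeR, DESeq2, limma-voom, other pseudocounts, no filter, TMM or total-read scaling, and without both libraries numbered 3. edgeR with TMM called 1686 and 1663 genes on the recovered reads, of which 1674 and 1611 were also called by limma. The replicate block, which pairs same-numbered samples, raised the counts to 2498 and 2208. It raised counts within lists as well, for example to 40 lower and 0 higher of 76 ribosomal protein genes. For the 25 cholesterol synthesis genes it gave 10 higher and 0 lower. It called the basal, lung metastasis and axon guidance lists and TRIM29, TGM1, ESAM and ERBB2 in addition, and changed no other call of a list or named gene. Leaving out 1 library gave 1017 to 1766 higher and 799 to 1547 lower genes, with the lowest counts without CD104high replicate 1 (1017 and 799). Without CD104high replicate 2 they were 1120 and 901, and without CD104low replicate 2, 1278 and 1030, where fewer samples were fitted. An adjusted p of 0.01 left 826 and 610 genes, and a log2 fold change of at least 1 left 333 and 35, both by construction. limma without the mean-variance trend called 936 lower genes, and the cause was not tested. Removal of the length and GC trend gave 3047 lower genes, or 3979 with the replicate block, in a form that also shifts the median of all genes to −0.06. With library means kept and the replicate block, 2734 were higher and 2574 lower, against 1886 and 1968 without the block. ITGB4 passed in every alternative run, at log2 fold changes of 2.28 to 2.71. Gene lists called numbered 11 to 21 against 15, except for 0 with an estimated correlation, with or without the replicate block. Without the block, estimated correlations lay between −0.020 and −0.007 for the matrix protease, luminal, mesenchymal, MLL3/MLL4 and epithelial lists. These are under the preset 0.01, so a higher correlation between members does not account for the loss of their calls. With an estimated correlation camera refers its statistic to the residual degrees of freedom of the fit, 4 without the block and fewer with it. The preset form does not, so a lost call is not by itself evidence of correlated members. Of 146 named genes, 117 kept their call in all alternative fits run for them, while the stricter limits on adjusted p and fold change were applied to the counts only. ARHGEF17, a YAP/TAZ target at 0.28 in limma, turned to −0.032 with the length and GC trend removed, with and without the replicate block, in the form that also moves library means, and was 0.043 with library means kept. The cause was not tested. Lists that were not called with all libraries but were with 1 left out are named with the results. At this depth, genes near the minimum of 10 were called only at large fold changes.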

Other observations

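Ribosome biogenesis factors, a list of 48 genes chosen after the largest falls, CCDC86 among them, were seen, were lower in CD104high almost without exception. Of the 48, 42 were lower over all genes in limma, 0 were higher, and 48 had a log2 fold change below 0, with a median of −0.54. POLR1E, a subunit of RNA polymerase I, fell by 0.79 (SE 0.07, adjusted p = 0.000214), UTP4 by 0.79, DDX21 by 0.68 and FBL, the methyltransferase of box C/D small nucleolar RNPs, by 0.57. The abundant nucleolar proteins NPM1 and NCL fell by 0.57 and 0.47. The 6 members that did not pass were RRN3, DDX56, UBTF, PPAN, RRP1B and NOP2, all named after their values were seen.

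Of the tests below, the list of ribosome biogenesis factors, the scalings, the length and GC corrections and the left-out library for ribosomal protein genes were chosen after the data were seen. Of 76 ribosomal protein genes, 25 were lower in CD104high and 51 did not pass (camera adjusted p = 0.43 with an estimated correlation, fry adjusted p = 0.0774). The length and GC trend does not account for the whole shift, since the median was −0.29 with the replicate block after its removal and −0.22 with library means kept, against −0.24 before, but 337 other genes as short and as high had a median of −0.10, so part of it may go with such genes. The choice among the scalings used does not either, with −0.22 under total-read scaling. Total-read and TMM scaling moved the median of all genes only from 0.009 to 0.028 and 0.005, so a larger scaling error was not tested. The median closest to 0 was −0.14 without CD104low replicate 1, which carried much of the shift. The bootstrap SE of that median, 0.01, is over members with an estimated correlation of 0.75, not over libraries. In mean level, pairs 1 to 3 differed by −0.48, −0.16 and −0.13, so 1 library did not make the whole shift. Lower growth-related transcription in CD104high cells may account for the pattern, as the ribosome biogenesis factors had a median of −0.54 (camera adjusted p = 3.46e-27 when adjusted with the fixed lists, but adjusted p = 0.103 with an estimated correlation). This is a hypothesis found and tested on the same libraries, and differences in cell density or in the time spent in the sort stay open, as no label gives them.

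The type I interferon response genes were higher in CD104high, with a median of 0.87. The median was 0.81 in the fit with the replicate block after removal of the length and GC trend, and 0.81 at the lowest without 1 library, so neither accounts for it. A difference between the cell states, or a response to the treatment or to the sort that differed between the groups, may account for the pattern, and these stay open and untested, since untreated and unsorted cells were not analysed here.

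The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 1730 higher and 1625 lower genes, and it alone (1 of 10 splits, for the higher and for the lower count) gave as many, with a highest count of 0 among the others in limma. Those splits gave between 52 and 826 genes at an unadjusted p under 0.05, against 5292, and 0 genes with edgeR. The 3 other splits that part all 3 numbered pairs also gave 0 genes with limma and with edgeR, and the others part 1 pair each. Every split but the real one mixed CD104high and CD104low libraries in both groups. The difference between CD104high and CD104low then adds to the spread within groups, so the counts of 0 do not measure what chance would give.

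In the authors' deposited table, 2054 genes were higher and 2042 lower at an adjusted p under 0.05, of 13831 with an adjusted p. Of these, 1661 and 1597 were also called by limma, and 0 were called in opposite directions.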
